A study of Caenorhabditis elegans with 2 samples.

How the data were processed

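The 2 samples were ChIP-seq libraries of whole young adult *C. elegans* of strain OP638, with tagged ATF-7. The labels differ on the antibody, since the description says that an anti-GFP antibody was used and the antibody field names atf-7, and the description was followed. They are biological replicates 2 and 3 of 1 group, from separate biosamples per the labels. With 1 group there is no comparison between conditions and p-values describe positions in the genome, not animals.

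Per the labels and the listing deposited with each sample, the authors mapped the reads to builds ce10 and ce11, called relaxed peaks for each replicate and for the pooled reads against a control, and derived the list of optimal IDR peaks from these 3 relaxed lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here, and the control itself was not analysed here. The relaxed lists in ce11 held 28126 peaks for replicate 2, 30000 for replicate 3 and 30000 for the pooled reads, and every IDR peak was also in the pooled list. The deposited signal values are the authors' value per peak relative to the control. Their level is not comparable between lists, so they were used to rank, filter and describe peaks within a list, and to correlate ranks between the replicates. The deposited −log10 q values were at their ceiling in all IDR peaks and were not used for ranking. Read depth is not given in the files, so no value here carries a depth-based limit, and the intervals cover counting error only. The interval of a percentage is the exact Clopper-Pearson interval at 95%.

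The ce11 lists were the main data. They were joined to the WBcel235 genome, the same assembly as ce11, and its Ensembl annotation of 19973 protein-coding genes on the 6 nuclear chromosomes, with 29314 transcript 5′ ends. All peaks lay within the chromosome lengths of this assembly. The ce10 lists entered only alternatives that need no genome. Coordinates are given from 1. A promoter was the span from 1000 bp upstream to 200 bp downstream of a transcript's 5′ end, and a gene was bound when an IDR summit lay in a promoter of it. A peak between divergent genes was assigned to both. Groups of near-identical genes, such as histones and some heat shock genes, are uncertain, since reads could be shared between copies.

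Chance values for overlaps and shares came from 1000 circular shifts of the summits, each chromosome by its own random distance. For annotation classes 200 shifts were drawn. Motifs were searched on both strands within 100 bp of the summit and compared with the window centred 500 bp toward the higher coordinate by an exact McNemar test, and the flank percentages of single motifs are means of both sides. The flank values of the 6-base words, of the base composition and of the share with at least 1 of the E-box, GA repeat and GATA sites are those of the window toward the higher coordinate alone. The 9 motifs formed 1 family and the 2080 words another, each with Benjamini-Hochberg adjustment at 0.05. For 6-base words a difference of at least 5 percentage points was also required. Motif shares of promoter peaks were compared with matched positions in unbound promoters by Fisher's exact test. Signals of peaks with and without the CRE were compared by a permutation test of the difference of medians on the log2 scale, which was taken here of the authors' signal, with 100000 resamples, and its SE came from 2000 bootstrap draws. The SD of rho came from 200 bootstrap draws over peaks. Gene lists with 3 or more genes were tested by Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over 38 lists, and odds ratios had 0.5 added to each count. The neighbourhoods of *atf-7* and *unc-119* were compared with those of all protein-coding genes, by the number of relaxed peaks within 20 kb, with no test.

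The gene lists, the motifs, the tests and the main alternatives were fixed before the data were examined. The genes named are *atf-7* and *unc-119*, the 10 IDR peaks with the highest signal in a promoter, each named by the nearest 5′ end, the up to 4 bound members with the highest signal of each list that passed, and all bound members of the stress MAP kinase, p38 effector and bZIP lists. Unbound *pmk-1*, *sek-1*, *nsy-1* and *clec-85*, *cct-5*, where IDR peaks lie, and *rps-1* were named after their values were seen. Of 31 bZIP gene names 30 were found in the annotation, and the heat shock list gave 17 genes from 15 matched names.

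The alternatives were other distances and windows, the 1123 IDR peaks with the highest signal, the 2247 strongest peaks of each replicate in place of the IDR list (called without replicate 2 or without replicate 3), circular shifts and random lists matched on upstream spacing (10000 lists, 10 bins) for the gene lists, and ce10. Alternatives without peaks within 20 kb of *atf-7*, without tRNA peaks and with overlapping peaks merged were added after the data were seen. The statistic of the shift test of gene lists was also changed after its first results were seen. Its first form, an odds ratio, gave the smallest possible p to lists with no bound gene, because shifted summits hit fewer promoters than real ones. It was replaced by the share of all bound genes that a list holds, and fewer lists passed with it than with the first form.

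The Fisher and shift tests of lists, the promoter, CRE, word and signal tests and the replicate overlap were tested on simulated data with fixed seeds. Other steps, such as the lists matched on upstream spacing, the rank correlation and the comparison with unbound promoters, were not. A list of 81 genes bound 5 times as often as others was called in 100% of 100 draws, one of 22 genes in 79% and one of 16 genes in 62%, and 0.258% of unchanged lists were called. In these draws each gene was bound independently of its neighbours. Where neighbouring genes share a peak, these percentages of the Fisher test need not hold. The shift test of lists had a raw p under 0.05 in 0.132% of 760 unchanged lists. In 40 draws each of 500 peaks, the promoter test called 7.5% of sets of random peaks and 100% of sets with an added promoter share. For a CRE planted in 11.0% of 1998 windows, 11.1% was recovered. Of summits moved by at most 50 bp in 60% of 1000 peaks, 60% were recovered as shared. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.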

Results

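ATF-7 is a bZIP transcription factor of the ATF and CREB family in the nematode *Caenorhabditis elegans*, known as a target of the p38 kinase PMK-1 in innate immunity. Its binding was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole young adult worms of strain OP638. This strain carries an integrated transgene, wgIs638, that expresses ATF-7 with a C-terminal GFP-FLAG tag, together with a rescue of the *unc-119* mutation, and the description in the labels gives an anti-GFP antibody for the precipitation, while their antibody field names atf-7. The data came from 1 group with 2 biological replicates, numbered 2 and 3 in the labels, and no other condition, so the comparisons were made between the replicates and between bound positions and the rest of the genome. The authors called peaks on each replicate and on the pooled reads, and kept a list of peaks past a threshold on the irreproducible discovery rate (IDR). This list held 2247 peaks in genome build ce11, and they are called IDR peaks here. Their signal, the authors' own value per peak, ran from 104.6 to 1585.89 with a median of 149. The read depth of the libraries is not known from the files, and peaks from unmodified worms were not analysed here.

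The strongest IDR peak at a promoter lay on chromosome III at 4899571 to 4900146, in intergenic sequence 631 bp upstream of *tag-340*, with a signal of 1585.89 in the pooled reads, 551 in replicate 2 and 1029 in replicate 3. The next were at *serp-1.1* (X:15841083-15841482, 294 bp upstream, signal 1326), at *tasp-1* (III:10759057-10759481, 43 bp upstream, signal 1102) and in the 5′ UTR of *Y43F8B.2* (V:19522492-19523159, signal 1064). *F02E9.5* on chromosome I (signal 1056), the ribosomal protein gene *rpl-3* on III (1051), *dhs-25*, of the short-chain dehydrogenase family, on X (906), *K11D12.14* on V (777), *Y17G9B.5* on IV (749) and *nspc-17* on X (711) completed the 10 strongest promoter peaks. Of these 10, the peaks at *Y43F8B.2*, *F02E9.5*, *dhs-25* and *K11D12.14* had the full cyclic-AMP response element (CRE) TGACGTCA, the palindrome bound by ATF and CREB dimers, within 100 bp of the summit. The peak of *Y17G9B.5* also lay 288 bp upstream of the ribosomal protein gene *rpl-20*, so the list of peaks does not say which of the genes it belongs to.

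The replicates shared many of their strongest peaks. Of the 2247 strongest peaks of each replicate, 60.8% had a summit within 100 bp of a summit among the 2247 strongest of the other, against a mean of 0.465% when one list was shifted around its chromosomes (1000 circular shifts, one-sided permutation p = 0.0010, the smallest these shifts can give). With summits within 50 bp the share was 46.1%, and within 200 bp it was 67.8% of the peaks of replicate 2. The IDR list was derived from the lists of these replicates, so its peaks are found in them largely by construction. A summit of replicate 2 lay within 100 bp of 2139 IDR peaks (95.2%) and a summit of replicate 3 within 100 bp of 2197 (97.8%), and among the 2247 strongest peaks of each replicate the shares were 73.1% and 84.9%. Across the 2092 IDR peaks with a summit in both, Spearman's rho between the signals of the replicates was 0.582 (bootstrap SD 0.0170). The peaks are not independent replicates, so no p is given for it. The signal of replicate 3 over that of replicate 2 had a median log2 ratio of 0.77 and an SD of 0.546 across peaks. Each list has its own scale, so this median is no difference in binding.

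**Figure D1:**
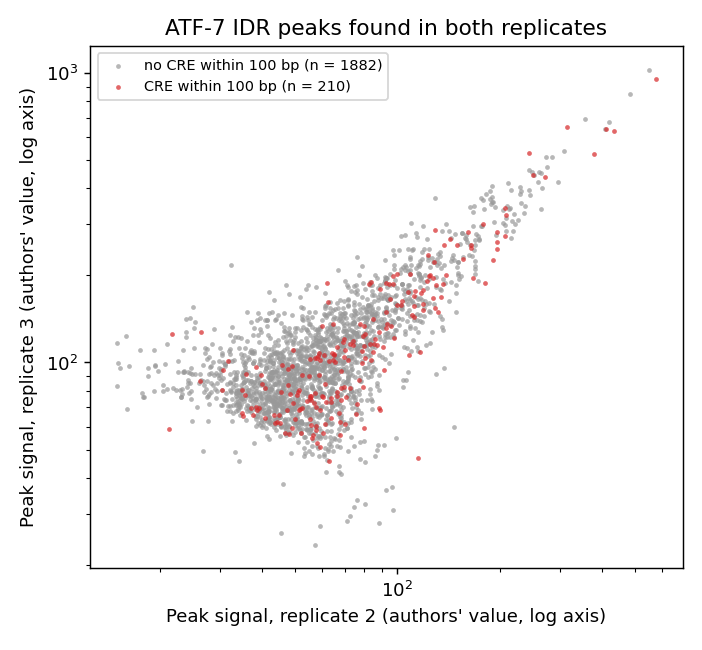
Signal of each IDR peak in replicate 2 (x axis, authors' value, log scale) against replicate 3 (y axis, authors' value, log scale), for the 2092 peaks found in both. Each point is a peak, in red where the CRE lay within 100 bp of the summit, and the ranks of the replicates had a Spearman's rho of 0.582.

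ATF-7 peaks gathered at promoters. Of the 2247 IDR summits, 1103 (49.1%, exact 95% interval 47 to 51.2) lay between 1000 bp upstream and 200 bp downstream of the 5′ end of a protein-coding transcript, 1.90 times the 25.8% (SD 0.944) of shifted summits (two-sided permutation p = 0.0020, the smallest 1000 shifts can give). These promoter peaks were assigned to 1245 of 19973 protein-coding genes (6.23%), which are called bound here. The median position of the promoter peaks was 213 bp upstream of the nearest 5′ end, and 86.9% were upstream of it. The window reaches 1000 bp upstream and only 200 bp downstream, so most peaks in it would lie upstream by construction. Intergenic sequence held 58.2% of the summits against 37.6% of shifted ones, and 5′ UTRs held 3.16% against 1.44%. Coding exons held 9.79% against 24.4%, introns 25.3% against 33.2%, and 3′ UTRs 3.56% against 3.34%.

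IDR peaks also gathered near tRNA genes. Summits of 183 IDR peaks (8.14%, exact 95% interval 7.05 to 9.35) lay within 200 bp of a tRNA gene, against 0.300% of shifted summits, a 27.1-fold excess (two-sided permutation p = 0.0020, the smallest 1000 shifts can give). They covered 201 of the 612 annotated tRNA genes, and their median signal was 143 against 149 for the other peaks. The CRE was found in 5 of the 183 tRNA peaks (2.73%, exact 95% interval 0.893 to 6.26), against 10.4% of the other peaks.

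The X chromosome held 491 IDR peaks (21.9%, exact 95% interval 20.2 to 23.6), the most of any chromosome, with 27.7 peaks per Mb against 17.8 on chromosome V and 26.6 on chromosome III. Among protein-coding genes, 205 of 2731 on X were bound (7.51%) against 1040 of 17242 on the autosomes (6.03%), an odds ratio of 1.27 (Fisher's exact test, two-sided p = 0.00375). The autosomes differed among themselves, from 4.67% on chromosome V to 8.07% on chromosome III, which lay above X. The test of X against the autosomes missed the threshold among the 1123 peaks with the highest signal (3.84% against 3.31%, odds ratio 1.17, Fisher's exact test, p = 0.154) and without the peaks near tRNA genes (6.77% against 5.87%, odds ratio 1.17, p = 0.0683). Of the tRNA peaks, 49.7% were on X, which holds 45.1% of the tRNA genes.

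The CRE was concentrated at the summits. TGACGTCA lay within 100 bp of 220 summits (9.79%, exact 95% interval 8.59 to 11.09), against a mean of 1.11% in windows of the same size centred 500 bp to either side (exact McNemar test, adjusted p = 1.55e-41, Benjamini-Hochberg over 9 motifs). Within 40 bp of the summits there were 172 CRE sites, 14.8 times the density found 300 to 500 bp away. The shorter CREB core TGACG lay at 40.4% of the summits against 21.2% in the flanks (exact McNemar test, adjusted p = 7.64e-48). In promoter peaks the CRE share was 9.52%, against 0.816% at positions matched in distance in promoters without a peak (Fisher's exact test, adjusted p = 3.45e-22). The scrambled control TCAGATGC was at 0.312% of the summits and 0.490% of the flanks (exact McNemar test, adjusted p = 0.904). Summit windows held more G and C bases, 42.9% against 35.7% in the flank windows toward the higher coordinate. The scramble has no CG, which the CRE and TGACG have, so it does not control for a difference in CG content.

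Sites of other factor families were also more frequent within 100 bp of the summits. The E-box CACGTG, bound by basic helix-loop-helix factors, was at 11.8% of the summits against 3.40% of the flanks (exact McNemar test, adjusted p = 8.02e-26). The GA repeat GAGAGAGA was at 8.86% against 1.69% (exact McNemar test, adjusted p = 6.38e-29). TGATAA, the site of the intestinal GATA factors, was at 28.0% against 18.1% (exact McNemar test, adjusted p = 1.99e-13). GA repeat and GATA sites did not peak at the summit itself. In the 20 bp bins on either side of it there were 57 and 63 GA repeat sites, against 109 at 80 to 100 bp toward the higher coordinate. GATA sites numbered 89 and 97 in these bins, against 118 at 80 to 100 bp toward the lower coordinate. The AP-1 site TGASTCA of Fos and Jun dimers was at 2.63% against 1.76% (exact McNemar test, adjusted p = 0.0206), which missed the threshold against unbound promoters (2.90% against 1.54%, adjusted p = 0.0631) and among the 1123 peaks with the highest signal (3.03% against 1.78%, adjusted p = 0.148). The C/EBP type site TTRYGYAA was less frequent at the summits, at 4.05% against 5.41% (exact McNemar test, adjusted p = 0.0393). It also passed without replicate 2, without replicate 3 and without peaks near *atf-7* (exact McNemar test, adjusted p = 0.0189, 0.0438 and 0.0393). In other settings the difference missed the threshold. The shares were 4.99% against 6.71% in unbound promoters (Fisher's exact test, adjusted p = 0.131), 4.45% against 5.43% among the peaks with the highest signal (exact McNemar test, adjusted p = 0.409), 4.12% against 5.23% without the tRNA peaks (adjusted p = 0.162) and 4.07% against 5.37% with overlapping peaks merged (adjusted p = 0.0595). The SKN-1 type site WWTRTCAT was at 10.01% against 9.50% (exact McNemar test, adjusted p = 0.920). The tests against unbound promoters were Fisher's exact tests, and p-values were adjusted by Benjamini-Hochberg over the 9 motifs.

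**Figure D2:**
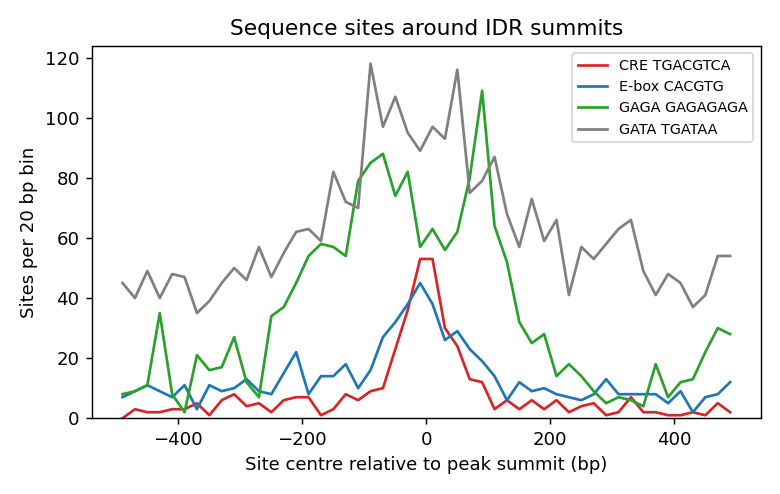
Number of sites per 20 bp bin (y axis) by the distance of the site's centre from the summit in bp (x axis), over the 2247 IDR peaks, for the CRE, the E-box, the GA repeat and the GATA site, one line each. CRE sites peaked at the summit, with 172 of them within 40 bp of it, while GA repeat and GATA sites did not peak at the summit itself.

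A search over all 2080 6-base words, counting a word and its reverse complement as 1, found 277 words whose share differed by at least 5 percentage points between the summit windows and the flank windows toward the higher coordinate (exact McNemar test, Benjamini-Hochberg adjusted threshold 0.05). Of these, 132 were more frequent at the summits. They included GAGAGA (33.2% against 11.0%), ACGTCA, part of the CRE (21.1% against 6.45%), ACGCAG (17.7% against 3.52%), GACGTC (13.3% against 2.45%) and CTTATC, which overlaps the GATA site (19.3% against 7.21%). Of the 145 less frequent words, 114 had 5 or 6 A or T bases, and the summit windows had 42.9% G and C bases against 35.7% in the flank windows. With windows of 50 bp to each side, 118 words passed.

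Peaks with the CRE were slightly stronger. The median signal was 169 for the 220 peaks with the site and 147 for the 2027 without, a log2 difference of 0.20 (bootstrap SE 0.0559), or 1.15-fold (permutation test, 100000 resamples, two-sided p = 0.000120). In replicate 2 the log2 difference was 0.28 (permutation p = 2.0e-05, the smallest these resamples can give) and in replicate 3 it was 0.11 (permutation p = 0.0394). With the 2247 strongest peaks of each replicate in place of the IDR list, the order of the replicates turned, with 0.12 in replicate 2 (permutation p = 0.00396) and 0.18 in replicate 3 (permutation p = 0.000920).

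**Figure D3:**
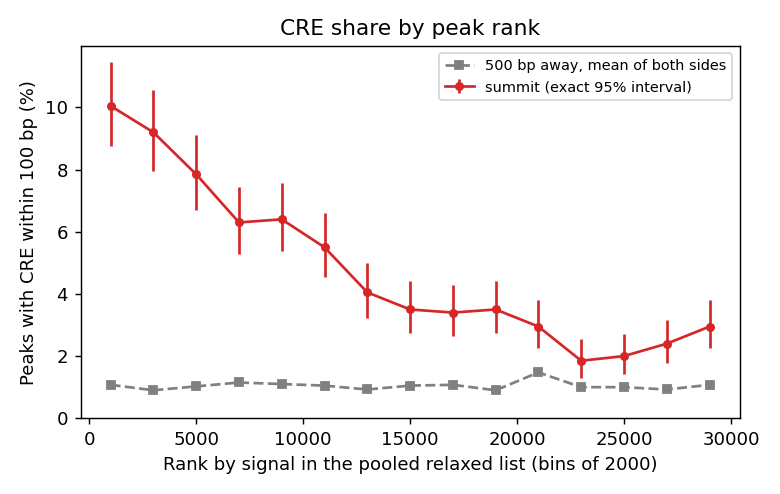
Percentage of peaks with the CRE within 100 bp of the summit (y axis, with exact 95% intervals) by rank in the authors' pooled list of relaxed peaks, in bins of 2000 peaks (x axis), and the mean of the windows 500 bp to each side. The share was 10.1% in the first bin and 2.95% in the last, and the flank windows stayed between 0.900% and 1.48%.

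Genes of bZIP transcription factors, the family of ATF-7 itself, were bound far more often than other genes. Of 30 bZIP genes, 16 had a promoter peak (53.3%, exact 95% interval 34.3 to 71.7), against 6.16% of all other protein-coding genes (odds ratio 17.3, Fisher's exact test, adjusted p = 5.69e-11, Benjamini-Hochberg over 38 lists). Fisher's test takes genes as independent, and the list also passed when the summits were shifted along the chromosomes, which keeps neighbouring genes together (circular shifts, adjusted permutation p = 0.019). The highest signal was at *xbp-1*, the transcription factor of the unfolded protein response (III:4193582-4193982, summit 56 bp upstream, signal 708, with the CRE). It was followed by *zip-2*, which acts in the response to infection (III:833683-834060, in an intron, signal 594), *crh-1*, the worm's CREB (III:11689438-11689703, in a 5′ UTR, signal 398, with the CRE), and *cebp-1*, of the C/EBP family (X:1453871-1454197, 175 bp upstream, signal 397, with the CRE). *skn-1*, a regulator of detoxification, *atf-7* itself, *zip-10*, *zip-12*, *atf-4*, *atf-6*, *jun-1*, *zip-1*, *crh-2*, *zip-4*, *let-607* and *zip-11* were also bound, with signals of 280 to 114. No summit of replicate 2 lay within 100 bp of the *zip-12* peak, and none of replicate 3 within 100 bp of the *jun-1* peak.

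Of the lists of stress genes, those of stress MAP kinase signalling, the endoplasmic reticulum stress response and heat shock passed Fisher's exact test. None of them passed under circular shifts (adjusted permutation p = 0.177, 0.0607 and 0.177). Bound members are shared with the bZIP list, so these results are not independent of it. They are *skn-1* and *atf-7* in stress MAP kinase signalling, and *xbp-1*, *atf-4* and *atf-6* in the endoplasmic reticulum stress response. The mitochondrial stress response (3 of 11 genes bound, Fisher's exact test, adjusted p = 0.0611) and oxidative stress genes (1 of 22, adjusted p = 1) did not pass. Of 22 genes of stress MAP kinase signalling, 7 were bound (31.8%, exact 95% interval 13.9 to 54.9, Fisher's exact test, adjusted p = 0.00169). These were *nipi-3*, of the Tribbles kinase family (signal 337), *skn-1* (280), *egl-30*, the Gq alpha subunit (262), the kinase gene *dlk-1* (241), *atf-7* (240), the protein kinase C gene *tpa-1* (132) and *vhp-1*, a MAP kinase phosphatase (122). No summit of replicate 3 lay within 100 bp of the *dlk-1* peak. The p38 gene *pmk-1* was not bound, with its nearest summit 3160 bp from the 5′ end, and the nearest summits of *sek-1* and *nsy-1* were 6549 bp and 3211 bp away. Of 29 genes of the endoplasmic reticulum stress response, 10 were bound (34.5%, Fisher's exact test, adjusted p = 4.36e-05), led by *xbp-1*, *cdc-48.1* (signal 697), the BiP gene *hsp-3* (432) and *uggt-1* (275). Of 17 heat shock genes, 6 were bound (35.3%, Fisher's exact test, adjusted p = 0.00214), led by the HSP70 family genes *F44E5.4* and *F44E5.5*, which share a peak between them (632), *hsp-1* (424) and *dnj-13* (423). With promoters of 500 bp to each side, 4 of the 22 stress MAP kinase genes were bound and the list did not pass (Fisher's exact test, adjusted p = 0.0618).

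Ribosomal protein, translation factor and respiratory chain genes were bound more often by Fisher's exact test. The ribosomal protein and respiratory chain lists also passed under circular shifts (adjusted permutation p = 0.019 each) and the translation factor list did not (adjusted p = 0.110). Of 81 cytosolic ribosomal protein genes, 23 were bound (28.4%, exact 95% interval 18.9 to 39.5, Fisher's exact test, adjusted p = 5.71e-09), led by *rpl-3*, *rpl-20* (signal 749), *rpl-15* (705) and *rpl-35* (576). Of 40 translation factor genes, 9 were bound (22.5%, Fisher's exact test, adjusted p = 0.00309), among them *iff-2* (415), *eef-1A.2* (348), *eif-3.C* (260) and *eef-2* (242). Of 47 respiratory chain genes, 13 were bound (27.7%, Fisher's exact test, adjusted p = 3.67e-05), with the highest signals at *cox-5A* (525), *nduf-2.2* (318), *atp-1* (254) and *cox-5B* (241). None of the peaks of these ribosomal protein, translation factor and respiratory chain genes had the CRE within 100 bp of the summit. The site was uncommon at other bound genes too, at 110 of 1222 bound genes outside the ribosomal protein list. None of these lists differed from other bound genes in its CRE share by Fisher's exact test. With 23, 9 and 13 bound genes, even complete absence of the site could not pass (unadjusted p = 0.255 for the ribosomal proteins, Fisher's exact test). These tests therefore cannot decide whether the absence of the CRE sets the lists apart. Of the mitochondrial ribosome, 4 of 70 genes were bound (5.71%), and of the aminoacyl-tRNA synthetases 2 of 32 (6.25%, Fisher's exact test, adjusted p = 1 each).

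Lists of intestine markers, vacuolar ATPase, autophagy and vitellogenin genes also passed Fisher's exact test. None of them passed under circular shifts (adjusted permutation p = 0.187, 0.110, 0.268 and 0.110). Of 24 intestine marker genes, 6 were bound (25%, Fisher's exact test, adjusted p = 0.00934), led by the desaturase gene *fat-6* (signal 252), *act-5* (211), the GATA factor gene *elt-2* (175) and *asp-1* (153). Of 20 vacuolar ATPase genes, 6 were bound (30%, adjusted p = 0.00408), led by *vha-13* (205), *vha-12* (172), *vha-2* (135) and *vha-8* (123), of 29 autophagy genes 6 (20.7%, adjusted p = 0.0202), led by the Atg8 family gene *lgg-2* (268), *epg-7* (236), *lgg-1* (196) and *atg-9* (155), and of 6 vitellogenin genes 3 (50%, Fisher's exact test, adjusted p = 0.0114), namely *vit-5* (177), *vit-2* (141) and *vit-3* (111.96). The vacuolar ATPase and autophagy lists did not pass in replicate 2 alone (adjusted p = 0.526 and 0.0653), and the vitellogenins passed in neither replicate alone (adjusted p = 0.108 in replicate 3 and 0.106 in replicate 2, exact test). Among markers of other tissues, 0 of 16 muscle, 0 of 17 epidermis, 0 of 14 pharynx, 1 of 20 neuron and 1 of 31 germline genes were bound, and none of these lists passed (exact 95% upper bounds 20.6%, 19.5%, 23.2%, 24.9% and 16.7%). With promoters of 2000 bp upstream, 5 of the 20 neuron markers were bound and the list passed as bound more often (25% against 8.41% of other genes, Fisher's exact test, adjusted p = 0.0475).

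**Figure D4:**
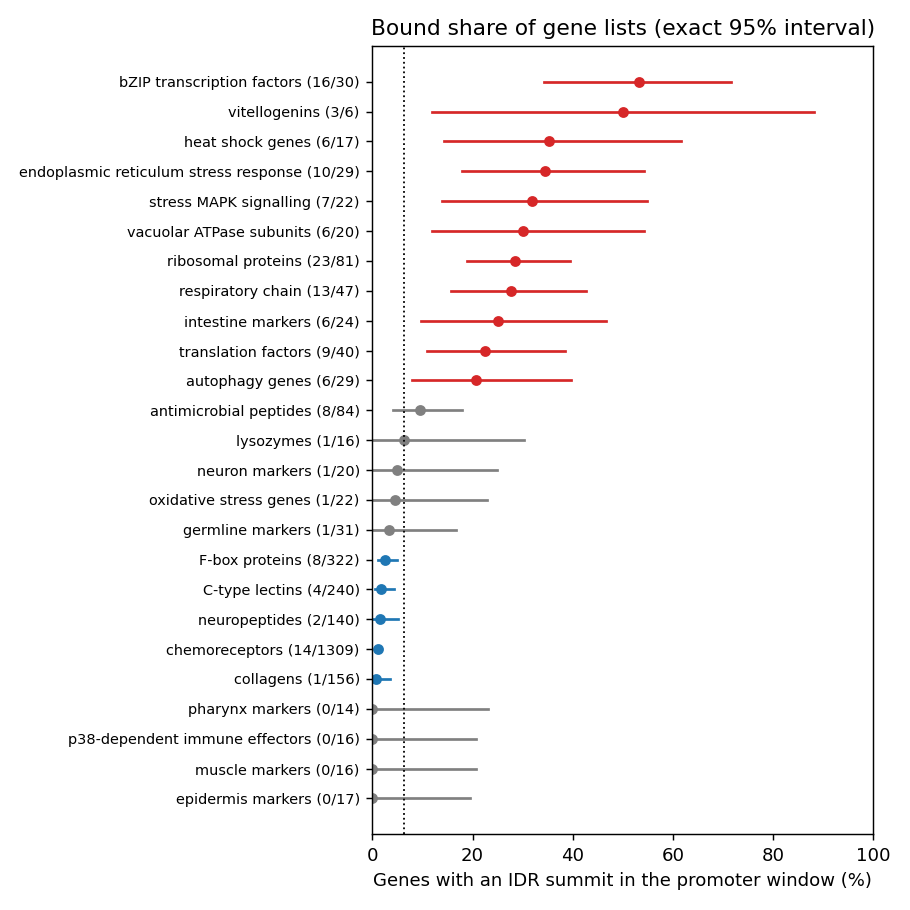
Percentage of genes with an IDR summit in the promoter window (x axis) for the gene lists that passed the test and some that did not, with exact 95% intervals and bound and tested genes in parentheses. Lists bound more often than other genes are in red, less often in blue and not past the test in grey, and the dotted line marks the 6.23% of all protein-coding genes.

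By Fisher's exact test 5 gene families were bound less often than other genes, and of these the chemoreceptors also passed under circular shifts (adjusted permutation p = 0.019). Collagens, C-type lectins, F-box genes and neuropeptides did not (adjusted permutation p = 0.110, 0.177, 0.261 and 0.217). Of 1309 chemoreceptor genes, 14 were bound (1.07%, Fisher's exact test, adjusted p = 4.52e-20), led by *sri-39* (signal 367), *srh-2* (355), *srh-269* (301) and *sre-23* (279). The same held for 1 of 156 collagen genes, *col-185* (0.641%, Fisher's exact test, adjusted p = 0.00408), for 4 of 240 C-type lectin genes (1.67%, adjusted p = 0.00408), namely *clec-126*, *clec-78*, *clec-265* and *clec-186*, for 8 of 322 F-box genes (2.48%, adjusted p = 0.00975), led by *fbxb-58* (signal 495), and for 2 of 140 neuropeptide genes (1.43%, adjusted p = 0.0302), *ins-39* and *nlp-40*. The neuropeptides did not pass in replicate 2 alone (Fisher's exact test, adjusted p = 0.153) or replicate 3 alone (adjusted p = 0.108). With promoters of 500 bp to each side neither the C-type lectins (2.50% against 5.18% of other genes, Fisher's exact test, adjusted p = 0.159) nor the neuropeptides (1.43% against 5.18%, adjusted p = 0.114) passed, and the neuropeptides also missed the threshold against lists matched on upstream spacing (adjusted permutation p = 0.0584).

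None of the 16 p38-dependent immune effector genes was bound (0%, exact 95% interval 0 to 20.6), against 6.24% of other genes (Fisher's exact test, two-sided p = 0.620, adjusted p = 0.822). Random lists of this size matched on upstream spacing held 1.07 bound genes on average, so a lower share was not detectable. On simulated data a list of 16 genes bound 5 times as often as others was called in 62% of 100 draws. Genes were bound independently of each other in these draws. The summit nearest to any of their 5′ ends lay 792 bp downstream of that of *clec-85*, outside the promoter window. In replicate 3 alone 6.25% were bound against 6.27% of other genes, and in replicate 2 alone 12.5% against 5.89%, neither past the test.

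In all, 16 of the 38 lists passed, 11 bound more often and 5 less often. Some lists share bound genes, such as *vit-2* in the intestine marker and vitellogenin lists, so these are not 16 independent results. Under circular shifts 4 lists passed, those of bZIP genes, ribosomal proteins, respiratory chain and chemoreceptors, each with a raw permutation p of 0.0020, the smallest 1000 shifts can give. The shift test was strict on simulated data, where 0.132% of 760 unchanged lists had a raw p under 0.05. Among the 1123 peaks with the highest signal 9 lists passed, and the vacuolar ATPase, autophagy, vitellogenin, C-type lectin, F-box, collagen and neuropeptide lists did not. Of the other lists, nuclear hormone receptors (24 of 269 bound) and antimicrobial peptides (8 of 84) had adjusted p of 0.157 and 0.450 (Fisher's exact test). Bound genes were also counted in the lists of histones (3 of 72), lysozymes (1 of 16), infection response genes (1 of 8), *pals* genes (1 of 38), cytochrome P450s (1 of 74), UDP-glucuronosyltransferases (5 of 67), glutathione S-transferases (4 of 44), MATH and BATH proteins (1 of 73), major sperm proteins (0 of 31) and proteasome subunits (2 of 33), none of which passed. Lysozymes passed in replicate 3 alone (5 of 16 bound, Fisher's exact test, adjusted p = 0.00685) but not in replicate 2 alone. The mitochondrial stress response passed with promoters of 500 bp to each side (Fisher's exact test, adjusted p = 0.0475). The MATH and BATH proteins passed, as bound less often, with promoters of 2000 bp upstream (1.37% against 8.46% of other genes, Fisher's exact test, adjusted p = 0.0444).

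The strain carries extra copies of *atf-7* sequence, which can add reads there whether or not the protein binds, so this locus was examined by itself. Within 20 kb of the centre of *atf-7* (III:4491627-4499045, minus strand), replicate 2 had 33 relaxed peaks, replicate 3 had 25 and the pooled list 26, against means of 11.4, 12.03 and 12.1 around all protein-coding genes. These counts exceeded those of 99.8%, 95.7% and 96.5% of gene windows. The ratio to the mean, averaged over the replicates, was 2.49 (SD 0.583, n = 2), and it was 3.52 within 10 kb and 1.59 within 50 kb. The same window held 13 IDR peaks against a mean of 0.911, with the strongest in an *atf-7* intron at 4496083 to 4496438 (signal 604), and others in introns of the neighbouring *cct-5* and upstream of *rps-1* (443). Around *unc-119* there were 5 relaxed peaks in replicate 2, 3 in replicate 3 and 3 in the pooled list, fewer than around most genes, and 1 IDR peak, at III:10902965-10903400 in an intron (signal 169, with the CRE). The peaks counted as promoter peaks of *atf-7* and *rps-1* lie in this region. Without the 13 IDR peaks of this window the same 16 lists passed.

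**Figure D5:**
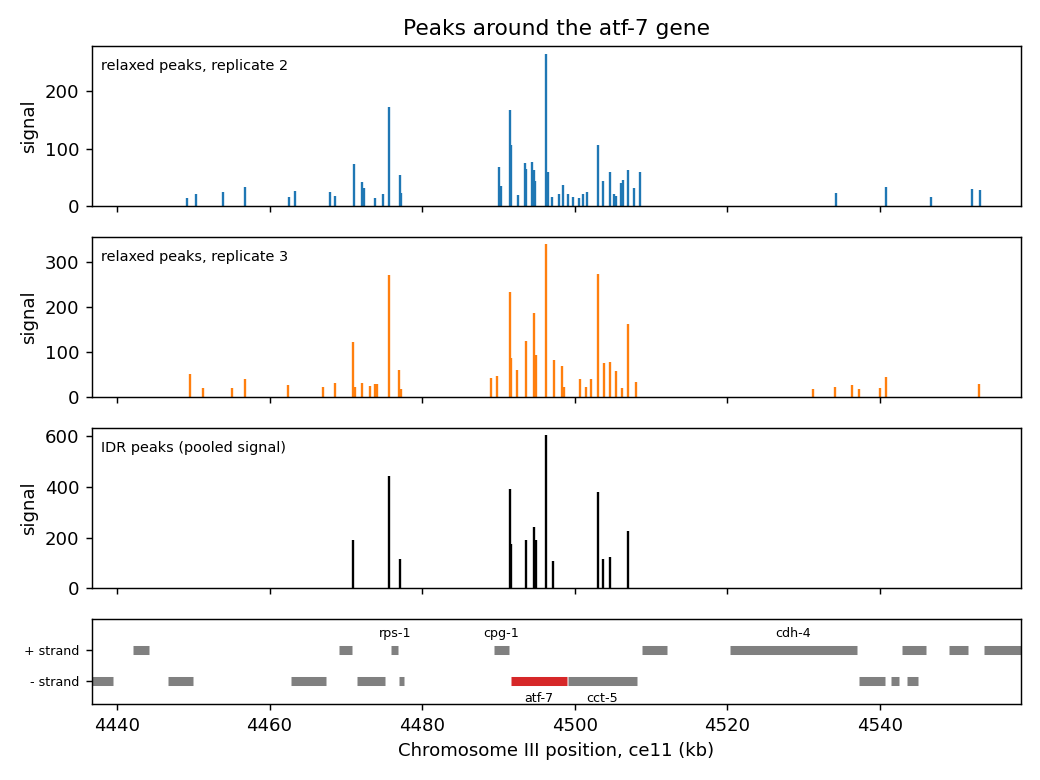
Signal (y axis, authors' value) of relaxed peaks in replicate 2 and replicate 3 and of IDR peaks, by position on chromosome III in kb (x axis, build ce11), with genes drawn below by strand and *atf-7* in red. The tallest line in each of the 3 panels stands in *atf-7*, at 264, 340 and 604.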

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

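The test in this part was chosen only after the result was seen. Relaxed pooled peaks outside the IDR list were not part of the main measurement, and they held the CRE more often than their surroundings. Of 27753 such peaks, 1218 (4.39%, exact 95% interval 4.15 to 4.64) had TGACGTCA within 100 bp of the summit, against 1.04% in the windows 500 bp away (exact McNemar test, p = 1.47e-146). In the pooled list, which has no IDR peak from rank 4001 by signal on, the share was 7.85% at ranks 4001 to 6000, 1.85% at ranks 22001 to 24000 and 2.95% at ranks 28001 to 30000. The authors' control was not analysed here, so the level of this site in peaks called without ATF-7 was not measured.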

How the results depend on the processing

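The settings without peaks near *atf-7*, without tRNA peaks and with merged overlaps, and the present form of the shift test of lists, were chosen only after results were seen. Across the main results, 71 values under an alternative kept their direction and side of the threshold or their size, 9 moved, 2 fell short of the threshold and 1 reversed. The rule for size was loose. Without replicate 3, 12 lists instead of 16 and 207 words instead of 277 counted as kept, as did 361 words among the peaks of highest signal. The replicate overlap counted as kept in every setting by its p alone, with shares from 46.1% to 69.3%. Single lists kept their call in 131 cases and missed the threshold, in the same direction, in 29. With the peaks of highest signal, 1123 peaks remained by construction, rho was 0.640, and 9 lists passed instead of 16. X held 22.4% of these peaks, and 19.4% of the peaks left without those at tRNA genes, and in both settings the test of bound genes on X against the autosomes missed the threshold (Fisher's exact test, p = 0.154 and 0.0683, with odds ratios of 1.17 instead of 1.27). The log2 signal difference of peaks with the CRE was 0.12 without replicate 3 and 0.18 without replicate 2, instead of 0.20. The rank correlation between the replicates' signals was 0.641 with summits within 50 bp and 0.563 within 200 bp. Windows of 50 bp gave 118 words instead of 277, and circular shifts 4 lists instead of 16. The excess of relaxed peaks at *atf-7* was 3.52-fold within 10 kb and 1.59-fold within 50 kb. Leaving out a replicate gave a bound share of the p38 effectors of 6.25% to 12.5% instead of 0%, and the higher value, without replicate 3, lay above the 5.89% of other genes under that setting, which reverses the direction, while the lower, without replicate 2, lay just below the 6.27% of other genes there, with no test passed. Except for the peak count, the cause was not tested. No paired analysis was possible because the data hold 1 group. Depth is not given in the files, so whether deeper libraries would add peaks is not known.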

Other observations

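The shares of other non-coding RNA genes, the strong peaks outside promoters, the motifs of bound list members and the shuffled windows were tests or values chosen only after the results were seen. Summits also lay within 200 bp of genes of other non-coding RNAs more often than shifted summits did. The share was 3.65% for snoRNA genes (82 peaks, 0.184% by chance), 1.07% for snRNA genes (24 peaks, 0.0599%), 0.534% for miRNA genes (12 peaks, 0.123%) and 0.935% for lincRNA genes (21 peaks, 0.320%), each with a two-sided permutation p of 0.0020, the smallest 1000 shifts can give. Of the 10 strongest IDR peaks, 3 lay outside promoter windows. The peak nearest to *fos-1*, the worm's Fos (V:6000220-6000770, signal 1529), had the CRE and lay 3127 bp upstream of it. The others were 1985 bp upstream of *sup-26* (signal 1047) and 4987 bp upstream of *bcat-1* (signal 966, with the CRE). Among bound genes, 4 of 16 bZIP genes had the CRE at their peak (25%) against 8.62% of other bound genes. None of the tests of 4 motifs in the 11 lists bound more often passed the adjustment (Fisher's exact test, lowest adjusted p = 0.595).

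The excess of peaks at tRNA genes has candidate technical explanations, and no biological explanation was tested, since the design has 1 group. The first was signal gathered at highly transcribed loci without the ATF site, which was to give a CRE share no higher than in the flanks. The share was 2.73% with an exact interval of 0.893 to 6.26, against 1.37% in their flanks and 10.4% at other peaks. It was thus lower than at other peaks and, as a point value, higher than in the flanks. The interval holds the flank value and also values well above it, so this test cannot decide. Transcription was not measured, and this explanation stays open. The second, reads shared between repeated tRNA copies, stays open. A median of 26.5% of the 36-base words around these summits recurred in the genome, against 0% at other peaks, which lies between the bounds set for it. Most of the words recurred at only 2 of the 183 tRNA peaks (1.09%, against 0.581% of other peaks). At 27 of the 183, under 10% recurred. The read length is not known.

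The excess of relaxed peaks around *atf-7* may come from extra copies of the transgene insert. The lower of the replicates' percentiles was 95.7%, narrowly above the 95% set for this explanation. Replicate 3 was at 98.7% within 10 kb and at 87.7% within 50 kb. The same explanation predicted an excess around *unc-119*, where the lower percentile was 5.47%, so no excess was seen there. How much of this region the rescue carries is not known here, and the control was not analysed, so this count cannot decide. Binding of ATF-7 at its own gene stays open as well, and no biological explanation was tested.

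E-box, GA repeat and GATA sites were frequent at summits without the CRE, and 2 technical explanations were weighed. The first was base composition of promoters. Of promoter peaks without the CRE, 38.1% had at least 1 of the 3 sites, against 17.5% in the same windows with their bases shuffled. The single bases of these windows alone thus gave a lower share. The 3 sites were singled out for their excess at these same summits, so this comparison cannot decide whether the excess is particular to bound peaks. Shuffling breaks up repeats such as GAGAGAGA, so the order of bases and repeated sequence stay open. Matched positions of unbound promoters had 24.5%, but they were matched in distance and need not have the same base composition. The second was weak peaks near the threshold. The share was 43.5% in the stronger peaks without the CRE and 24.6% in their flanks toward the higher coordinate. These sites were singled out for their excess over the flanks across all peaks, so this comparison cannot decide. Of the weaker peaks without the CRE, 412 of 1031 had at least 1 of the 3 sites. The exact intervals of the stronger and weaker peaks overlapped, so the sites were not seen to gather in the weaker peaks. No biological explanation was tested, and other technical ones, such as signal at open chromatin in general, stay open. Of all IDR peaks, 1182 (52.6%) had none of the 4 sites.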
